A study of Mus musculus with 480 samples.

How the data were processed

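Single tdTomato-positive lung cells of 3 mouse reporter lines were studied, 160 per line and 480 in all, on 5 plates of 96 wells, 2 of which held more than 1 line. Per the submitters' notes, lungs were digested with collagenase, dispase and elastase, cells were sorted into single wells, and full-length cDNA was amplified by PCR and made into libraries with Nextera XT. Per the submitters' processing notes, reads were aligned to GRCm38 with HISAT2 and counted per gene with HTSeq; versions are not given in the sources used here. The deposited table holds the count of reads per gene and cell, as the authors made it, with no scaling and no molecular identifiers. It listed 53379 genes. Symbols and GRCm38 positions came from GENCODE M21 and matched 53274 gene identifiers; the 105 without a symbol held 0.00513% of reads. A further 80 identifiers that share a symbol with another were left out of naming. Columns were joined to samples through the column names in the labels, with the header's shift of 1 place to the left taken into account, and 0 columns were left unmatched. Line and annotated sub-type (BASCs, club cell, AT2, ciliated cell) were taken from the labels.

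Depth was 492096494 reads in all, with median reads per plate of 792600, 567752, 1109930, 1113770 and 1238090. Median mitochondrial shares were 2.98%, 3.35% and 4.05% in BASCs-Tracer, Scgb1a1-TD and Sftpc-TD. For each group the reads were summed over cells and given as CPM, scaled by all gene-assigned reads, so cells with more reads weigh more. Ratios are log2 of CPM with 1 CPM added, and folds are on that scale. Poisson intervals for CPM and Clopper-Pearson intervals for shares are at the 95% level. They hold counting error only, and cells of a line were not treated as replicates. Genes with 0 reads in a group are given as 0 CPM, without a bound. No test between groups was run and no number of changed genes is given, because no animal was named and each line counted as 1 sample. No doublet caller was run. Reads of near-identical genes (Lyz1 and Lyz2, Ly6a and Ly6i, the Cyp2, Scgb3a, Bpif and H2 families) may be shared between copies.

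Before the data were examined, 11 pairs of groups, 23 gene lists and the rules for naming genes were fixed. The pairs set lines against lines, BASCs against club or AT2 cells, ciliated against club cells, and BASCs of the lines against each other. The lists held markers of AT2, club, ciliated, AT1, basal, neuroendocrine, pan-leukocyte, alveolar macrophage, endothelial, mesenchymal, erythroid and pan-epithelial kind. Further lists held surfactant genes shared by AT2 and club cells, MHC class II, lipid and sterol synthesis, xenobiotic metabolism, airway secretory and host defence, and proliferation genes. The last held Notch, Wnt and FGF pathway, progenitor-associated, and dissociation and immediate early genes. List members with 5 CPM or more in either group counted as measured. Each median was placed among 10000 random lists matched on expression in 20 bins, as a description. The AT2 list lay at percentile 100 and the club list at percentile 0 for BASCs of BASCs-Tracer against club cells. Plate pairs used plates with 5 or more cells of a group.

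Named genes needed 50 CPM in the higher group, a read in 25% of its cells and the same direction in all plate pairs, and the 10 largest ratios per direction were named. Mitochondrial, ribosomal protein, Gm-number and Rik genes were left out. Up to 4 members per list with the highest level, and Scgb1a1 and Sftpc, were also named. Not every gene that met the rule is reported here. For BASCs against both other types, genes were ordered by the smaller of both log2 ratios. Presence of both Scgb1a1 and Sftpc was called at 10 reads after thinning each cell to 100000 reads, which left out 12 cells. Position between club cells of Scgb1a1-TD (0) and AT2 cells of Sftpc-TD (1) used genes 4-fold or more apart with 50 CPM or more. Per cell, AT2-list over club-list reads were taken without both genes.

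Alternatives were the mean over cells, median-of-ratios scaling, totals without mitochondrial genes and the 10 genes with most reads, 10 CPM added, 468 cells with 100000 reads and 2000 genes, no filter on low genes, each plate left out, and only plates with both lines. For single results they were 1 or 100 reads, presence without thinning, genes with 5 or more reads, position folds of 8 and 2, and sub-types set by the lists. Added after the data were seen were club cells of BASCs-Tracer against those of Scgb1a1-TD, AT2 or club cells of BASCs-Tracer as reference, a limit of 1000 reads, and leaving out cells with 50 CPM or more of leukocyte markers. Ratios and gene numbers counted as moved beyond 1.5-fold, the median position beyond 0.1, and shares outside the interval of the main value. A ratio counted as reversed when its sign changed, but only where the main ratio was 2-fold or more. The explanation tests in the closing part were all written after the results were seen.

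The steps were tested on simulated data with 50 genes changed at each of 4 folds among 2596. The share recovered within 1.5-fold was 94% at 2-fold, 98% at 4-fold, 94% at 8-fold and 88% at 16-fold, all in the right direction. Of 2396 unchanged genes, 1 was 2-fold or more off. A simulated position of 0.75, the only one tried, came back as 0.729. The simulation held no effect of animal, line, plate or carry-over, and its spread between cells was set, not fitted to these data. Its groups had 97 to 149 cells. It therefore gives no error rate for such effects or for the groups of 6 to 15 cells. Of 1000 random lists, 50 fell outside the central 95% of the matched lists, and 59 of 1000 lists of abundant genes did. Lists were first drawn from abundant genes only, and the drawing from all measured genes was set after that result. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.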

Results

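Gene expression was measured in 480 single tdTomato-labelled cells sorted from the lungs of mice of 3 reporter lines, with 160 cells per line. BASCs-Tracer labels a cell only after both a Dre recombinase driven by Sftpc and a Cre recombinase driven by Scgb1a1 have acted, Scgb1a1-TD needs the Cre alone, and Sftpc-TD needs the Dre alone. Sftpc encodes surfactant protein C of alveolar type 2 (AT2) cells and Scgb1a1 encodes the secretoglobin of airway club cells. Bronchioalveolar stem cells (BASCs) lie where the terminal airway meets the alveoli and are defined by carrying both products. Per the labels, each cell was annotated as BASCs, club cell, AT2 or ciliated cell. The cells lay on 5 plates of 96 wells. BASCs-Tracer filled plate 1 and 64 wells of plate 2. Scgb1a1-TD took 32 wells of plate 2, plate 3 and 32 wells of plate 4. Sftpc-TD took 64 wells of plate 4 and plate 5. The cells held 492096494 gene-assigned reads, with a median of 1000460 per cell and a range of 3379 to 3781974. A median of 4870 genes had a read, with a range of 986 to 8865. Median reads per cell were 778327 in BASCs-Tracer, 1082400 in Scgb1a1-TD and 1114750 in Sftpc-TD. No label named the animals, so each line counted as 1 sample, no test between lines was possible, and all values lack a replicate check. Intervals are at 95%, and because the reads come from PCR without molecular identifiers they cover counting error only.

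The first question was which annotated cell types each reporter marked. In BASCs-Tracer, 86.25% of the 160 cells were BASCs (Clopper-Pearson interval 79.9% to 91.2%). A further 15 cells were club cells (9.38%, 5.34% to 14.99%), 6 were AT2 cells (3.75%, 1.39% to 7.98%) and 1 was a ciliated cell (0.625%). Scgb1a1-TD was made up of 97 club cells (60.6%, 52.6% to 68.2%), 38 BASCs (23.75%, 17.4% to 31.1%), 24 ciliated cells (15%, 9.85% to 21.5%) and 1 AT2 cell. In Sftpc-TD, 93.1% of cells were AT2 cells (88.03% to 96.5%) and 11 cells were BASCs (6.88%, 3.48% to 11.97%). No club or ciliated cell was annotated in Sftpc-TD, where 0 of 160 cells allows a share of up to 2.28%. The share of BASCs was 88.5% on plate 1 and 82.8% on plate 2 in BASCs-Tracer. In Scgb1a1-TD it was 15.6%, 23.96% and 31.25% on plates 2, 3 and 4, and in Sftpc-TD 6.25% and 7.29% on plates 4 and 5. The annotation may rest on the same counts as the gene levels given here, so marker differences between sub-types describe it and are not independent of it. When each cell was placed by the highest of the AT2, club and ciliated marker lists, all 187 BASCs fell to AT2. Of the club cells, 91 of 97 in Scgb1a1-TD but only 5 of 15 in BASCs-Tracer had the club list highest, and 8 of those 15 lay near the limit.

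**Figure D1:**
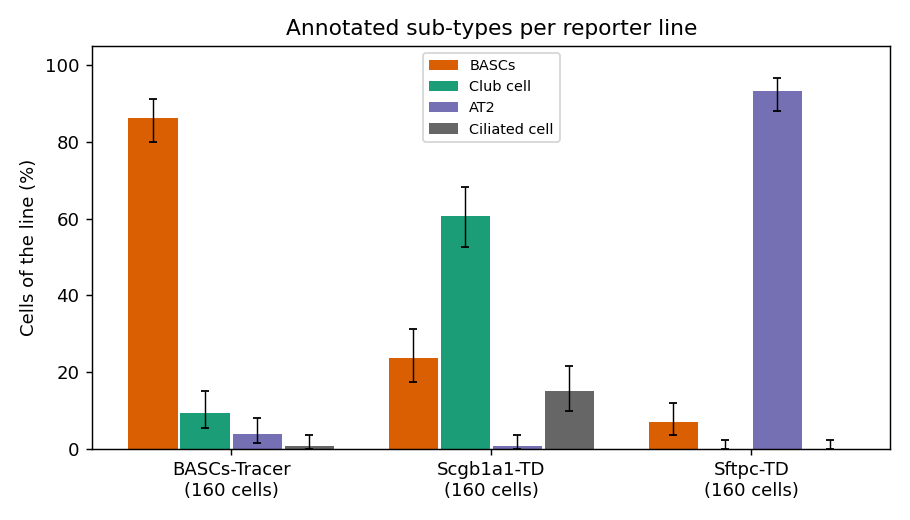
Share of the 160 cells of each reporter line (y axis, percent) with each annotated sub-type, as bars with 95% Clopper-Pearson intervals. BASCs made up 86.25% of BASCs-Tracer, 23.75% of Scgb1a1-TD and 6.88% of Sftpc-TD.

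The next question was whether BASCs carried both defining transcripts. Scgb1a1 (ENSMUSG00000024653, GRCm38 chromosome 19, 9083636 to 9087958, minus strand) stood at 13416 CPM (the count scaled by the total of gene-assigned reads; 13394 to 13438) in BASCs of BASCs-Tracer. It reached 258576 CPM in club cells of Scgb1a1-TD and 1285 CPM in AT2 cells of Sftpc-TD. Sftpc (ENSMUSG00000022097, chromosome 14, 70520949 to 70524081, minus strand) stood at 174513 CPM (174433 to 174592) in those BASCs, against 4062 CPM in the club cells and 160638 CPM in the AT2 cells. The pooled Sftpc level of the club cells was raised by few of them, as single cells ran from 219.7 to 165660 CPM. Scgb1a1 was 8464 CPM in BASCs of Sftpc-TD and 3518 CPM in BASCs of Scgb1a1-TD. With each cell thinned to 100000 reads, which left out 12 cells, both genes had 10 or more reads in all remaining cells of BASCs-Tracer (97.6% to 100%). The same held for all remaining cells of Scgb1a1-TD, including 24 ciliated cells, a type that should lack Sftpc, so 10 reads lay within background. In AT2 cells of Sftpc-TD the share was 74.3%, with 93.3% on plate 4, which also held Scgb1a1-TD cells, and 61.4% on plate 5. At 100 reads of each gene, the share was 87.2% (80.3% to 92.4%) in BASCs of BASCs-Tracer and 75.7% in BASCs of Scgb1a1-TD. It was 54.5% in the 11 BASCs of Sftpc-TD, 41.5% in club and 20.8% in ciliated cells of Scgb1a1-TD, and 25% in AT2 cells of Sftpc-TD. The 5 ciliated cells on plate 2, which also held BASCs-Tracer cells, had Sftpc at 1408 to 6291 CPM. Those on plate 3 had 320 to 1065 CPM, and those on plate 4, which held Sftpc-TD cells, 551 to 969 CPM. Club cells had 722 to 27225 CPM on plate 2 and 496 to 1614 CPM on plate 4. On plate 2, 100 reads of Sftpc thus also lay within background. Club and AT2 cells of BASCs-Tracer were closer to its BASCs, at 84.6% (11 of 13) and 66.7% (4 of 6). At 1000 reads, a limit added after the data were seen, 26.3% (19.1% to 34.7%) of BASCs of BASCs-Tracer held both, against 8.11% and 27.3% of BASCs of Scgb1a1-TD and Sftpc-TD. At that limit club cells of Scgb1a1-TD reached 6.38%, AT2 cells of Sftpc-TD 0.676% and ciliated cells 0 of 24, but club cells of BASCs-Tracer reached 38.5% (5 of 13) and its AT2 cells 16.7% (1 of 6). Median genes per cell at this depth were 3145 in BASCs of BASCs-Tracer, 3775 in club cells, 3083.5 in AT2 cells and 4303.5 in ciliated cells.

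**Figure D2:**
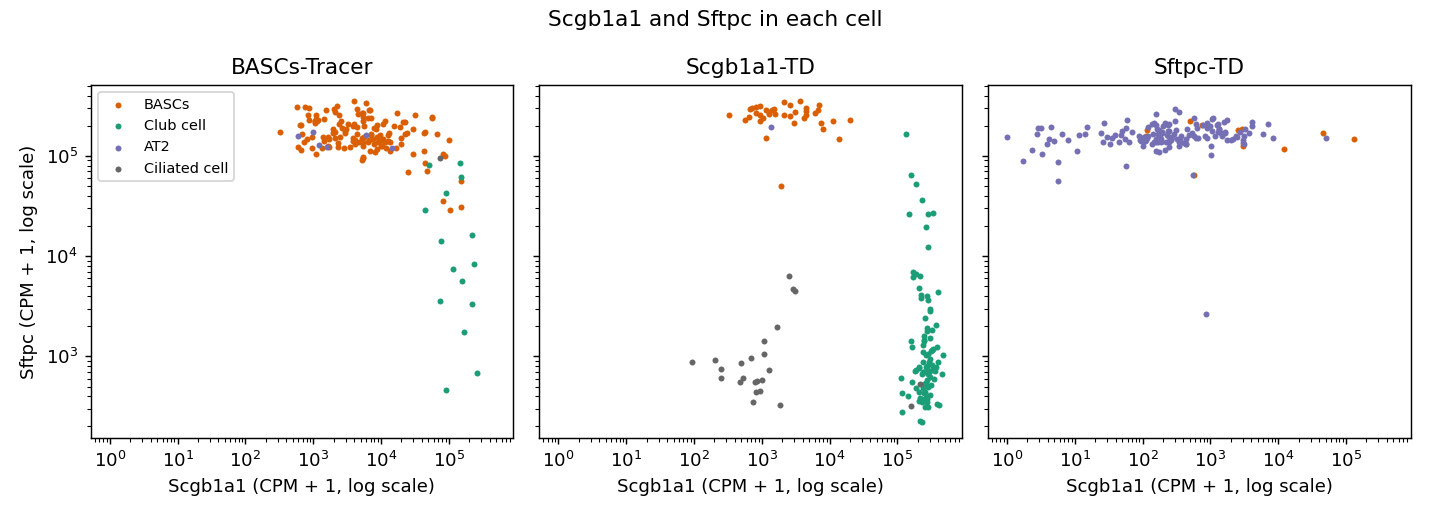
Scgb1a1 (x axis) and Sftpc (y axis) in each cell, in CPM with 1 added on log scales, 1 panel per reporter line, each point a cell coloured by annotated sub-type. BASCs lie at AT2-like Sftpc levels and spread over Scgb1a1 between AT2 and club cells, with median cells at 5394, 2014 and 2531 CPM of Scgb1a1 in BASCs-Tracer, Scgb1a1-TD and Sftpc-TD.

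Against club cells of Scgb1a1-TD, BASCs of BASCs-Tracer carried the AT2 programme at high level. All 16 AT2 markers lay 2-fold or more higher, with a median log2 ratio of 5.37 (4.81 to 5.55 over plate pairs). Sftpc was 42.95-fold higher and Lyz2, a lysozyme gene (chromosome 10, 117277331 to 117282321), 58.97-fold higher at 86639.5 CPM. For Sftpc the club pool was raised by a few cells, so the fold over most club cells was larger. Lyz1 was 218-fold, Hc, which encodes complement C5, 62.5-fold and the alarmin cytokine gene Il33 79.8-fold higher. All 7 MHC class II genes, which serve antigen presentation, also lay higher (median 5.63), with H2-Aa at 788 against 3.33 CPM, H2-Ab1 at 1092 against 12.5 CPM and the invariant chain gene Cd74 at 3277 against 51.8 CPM. Lipid and sterol synthesis genes were higher for 12 of 14 measured members (median 1.85). Itih4 (114.1-fold), Adam19 (71.3-fold) and St6galnac2 (64.6-fold) completed the 10 genes with the largest ratios.

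The club programme lay lower in the same BASCs. Of 20 measured club markers, 18 were 2-fold or more lower (median -4.24, -4.42 to -3.85 over plate pairs). Scgb1a1 was 19.3-fold lower, Scgb3a2 (chromosome 18, 43764289 to 43767399) was 148.5-fold lower at 150.975 against 22567 CPM, and the retinal dehydrogenase gene Aldh1a1 was 108.7-fold lower. Cyp2f2 (chromosome 7, 27119909 to 27133660), a cytochrome P450 of club cells, stood at 1273 against 32264 CPM. Xenobiotic metabolism genes were lower for 14 of 15 (median -2.68). Airway secretory and host defence genes were lower for 9 of 12 (median -4.48), including Bpifa1 (405-fold), the lactoferrin gene Ltf (123.1-fold) and Scgb3a1 of the club list (535-fold), while Lcn2 and Slpi lay higher. Chad, Ces1f, Acsm1 and Gabrp were 93.2-fold to 143.8-fold lower. The reference mattered: against the 15 club cells of BASCs-Tracer, a pair added later, the AT2 median was 3.14 and the club median -2.68. Scgb3a1, Bpifa1 and Ltf then turned to log2 ratios of 0.04, 1.41 and 0.25.

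Among the other lists in this pair, AT1 markers were higher for 7 of 12 (median 1.41), among them Ager at 1901 against 656 CPM, but their median was -0.02 against club cells of BASCs-Tracer. Surfactant genes shared by AT2 and club cells were higher for 4 of 5 (1.57), with Sftpd at 4864 against 1366 CPM. FGF pathway genes had a median of 1.01, with Fgfr2 at 477 against 145.7 CPM and Fgfr1 at 12.1 against 69.6 CPM. Wnt pathway (0.74), Notch pathway (-0.38), pan-epithelial (-0.23) and progenitor-associated genes (-0.56) held members on both sides. Of the Wnt pathway, Nkd1 stood at 105.2 against 3.07 CPM. Proliferation genes were lower for 8 of 12 (median -2.23), with Mki67 at 0.0375 against 21.05 CPM, but against club cells of BASCs-Tracer the median was 3.09 over the members measured in that pair and 0.17 over all 12. Ciliated markers had a median of -2.23 that became 1.04 without plate 3. Immediate early genes of tissue dissociation had a median of 0.59. Markers of other cells were low: pan-leukocyte genes had a median of 2.66 with Ptprc at 12.5 against 0.0103 CPM, alveolar macrophage genes 2.84, endothelial genes 1.78 and mesenchymal genes -0.79. Of the basal list only Krt14 was measured (3.14), and no neuroendocrine or erythroid gene reached 5 CPM.

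Against AT2 cells of Sftpc-TD, BASCs of BASCs-Tracer had the same AT2 markers at close levels and more of the club genes. All 16 AT2 markers lay within 2-fold (median -0.17), with Sftpc 1.09-fold higher. Of 16 measured club markers, 10 lay 2-fold or more higher and none lower (median 1.27, 1.04 to 1.75 over plate pairs). Scgb1a1 was 10.4-fold higher in the pool (median cells 5394 and 239.8 CPM), Scgb3a2 14.05-fold (log2 2.35 to 5.35 over plate pairs) and Cyp2f2 18.1-fold higher. Sox2, an airway transcription factor gene, stood at 15.9 against 0.0312 CPM, but only 19.6% of BASCs and 4.03% of AT2 cells had a read of it. Against the 6 AT2 cells of BASCs-Tracer itself, Scgb1a1 was only 3.56-fold, Cyp2f2 2.28-fold and Scgb3a2 1.70-fold higher. The club median in that pair was 1.11 over 17 members. Pigr, the receptor that carries immunoglobulins across epithelia, was 62.1-fold higher (180 against 1.91 CPM), and the tight junction gene Cldn4 48.8-fold higher. Of 6 measured progenitor-associated genes, Ly6a (10.2-fold) and Cd24a (15.1-fold) lay higher and Bmi1 lower, with a median of 1.44, and Kit, higher in the pool, changed sign over plate pairs. Esr1, the oestrogen receptor gene, stood at 96.9 CPM (95.03 to 98.8) against 3 reads, or 0.0156 CPM (0.00322 to 0.0456); reads of a recombinase transgene that holds an oestrogen receptor sequence were not told apart from Esr1.

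Several lists were close to level in this pair. Lipid and sterol synthesis (-0.00), xenobiotic metabolism (0.02), FGF pathway (-0.04), endothelial (-0.09) and pan-epithelial genes (0.28) had medians close to 0. AT1 markers were lower for 3 of 13 (-0.79), shared surfactant genes had a median of -0.34 and MHC class II genes one of 0.67. Airway secretory and host defence genes had a median of 0.80, with Pigr and Muc5b higher, and immediate early genes one of 0.18. Pan-leukocyte genes had a median of 3.18, and 7 BASCs (5.07%) and 1 AT2 cell (0.671%) held 50 CPM or more of these markers together. The Y-linked genes Eif2s3y and Ddx3y were at 92.2 and 72.8 CPM in BASCs against 0.0312 and 0.0416 CPM in AT2 cells. The X-inactivation transcript Xist was 30.4-fold lower in BASCs. Tex11, BC018473, Dbp, Cipc, Tef, Bmi1, Bicc1, Snw1 and Atp7a were 3.32-fold to 6.50-fold lower. No plate held both lines, so plate and line could not be told apart. Against the 6 AT2 cells of BASCs-Tracer the log2 ratio turned for Ly6a (-0.70), Xist (1.47), BC018473 (4.02), Dbp (3.86), Bmi1 (3.27) and Cipc (3.42).

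Some genes lay outside the range of both other types. BASCs of BASCs-Tracer exceeded club cells of Scgb1a1-TD and AT2 cells of Sftpc-TD in Hdc, the histidine decarboxylase gene, at 533 against 8.57 and 175 CPM, and in the matrix glycoprotein gene Thbs1, at 395 against 90.03 and 136.6 CPM. The others of the 10 genes with the largest ratios were Ly6i, Gkn3, Heatr1, Myc, Rerg, Rabep1, Ier5 and Odc1, each 2.63-fold to 8.08-fold above the higher of the other types. Rerg stood at 63.3 against 0.216 and 19.6 CPM, and the proto-oncogene Myc at 59.6 against 17.4 and 17.7 CPM. Club cells of BASCs-Tracer itself lay above its BASCs in Thbs1 (1346 CPM) and Myc (712 CPM). In the opposite direction, Timp3, an inhibitor of matrix metalloproteinases, was 258 CPM against 606 and 713 CPM, and Sec14l3 was 224 CPM against 2463 and 561 CPM. Vnn3, Snw1, Chchd3, Mapre2, Zfp445, Col23a1, Net1 and Klf15 were 2.25-fold to 3.31-fold below the lower of the other types. The 6 AT2 cells of BASCs-Tracer lay below its BASCs for Vnn3 (0.400 CPM), Net1 (2.40 CPM), Klf15 (7.81 CPM), Chchd3 (12.4 CPM) and Sec14l3 (146.4 CPM), and its club cells also did for Klf15 (19.8 CPM) and Chchd3 (15.5 CPM). Within Scgb1a1-TD, 5 of the 10 higher genes and 8 of the 10 lower genes kept a 2-fold difference between BASCs and club cells. Between BASCs and AT2 cells, 5 of the 10 higher genes kept it within BASCs-Tracer, not among them Hdc (367 CPM in its AT2 cells), Rerg (51.7 CPM) and Myc (36.04 CPM). Of those kept, Gkn3, Heatr1 and Rabep1 rest on few reads in the 6 AT2 cells, at 0.400, 0.801 and 1.80 CPM. Within Sftpc-TD 4 of the 10 kept it, and BASCs there held 0 CPM of Ly6i and Gkn3.

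The position of BASCs between both types was then measured over 440 genes that differed at least 4-fold between club and AT2 cells, with 0 set at club and 1 at AT2 cells. The median position of BASCs of BASCs-Tracer was 0.864 (10th to 90th percentile 0.490 to 1.09). Of these genes, 346 lay between both types, 90 lay beyond AT2 cells and 4 beyond club cells. Because the genes were picked by the gap between both end groups in these same cells, values in between are favoured. Genes that differ by line or sex between Scgb1a1-TD and Sftpc-TD were not removed. No position was computed for AT2 cells of BASCs-Tracer, so the count between both types cannot be read as a mixed state. Genes higher in AT2 cells had a median position of 0.911 (249 genes) and genes higher in club cells 0.780 (191 genes). Per cell, the log2 ratio of AT2-list to club-list reads, without Sftpc and Scgb1a1, had a median of 3.87 in BASCs of BASCs-Tracer. It was 4.25 in BASCs of Scgb1a1-TD, 3.96 in BASCs of Sftpc-TD, 3.42 in AT2 cells of Sftpc-TD, 4.08 in the 6 AT2 cells of BASCs-Tracer and -2.58 in club cells of Scgb1a1-TD. BASCs thus did not lie nearer to club cells than AT2 cells did on this score, in which Cbr2, at 9465 CPM in BASCs of BASCs-Tracer and 13919 CPM in AT2 cells of Sftpc-TD, has the most club-list reads. Club cells of BASCs-Tracer had a median of -1.63 and ciliated cells -4.48. Of BASCs of BASCs-Tracer, 11 (8.27%, 4.20% to 14.3%) fell between the 95th percentile of club cells and the 5th percentile of AT2 cells, and all others lay above the latter. By the way the limit was set, 8 AT2 cells of Sftpc-TD (5.41%, 2.36% to 10.4%) lay in the same zone, and the intervals overlap. With Sftpc and Scgb1a1 counted in, the share between was 21.1%.

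**Figure D3:**
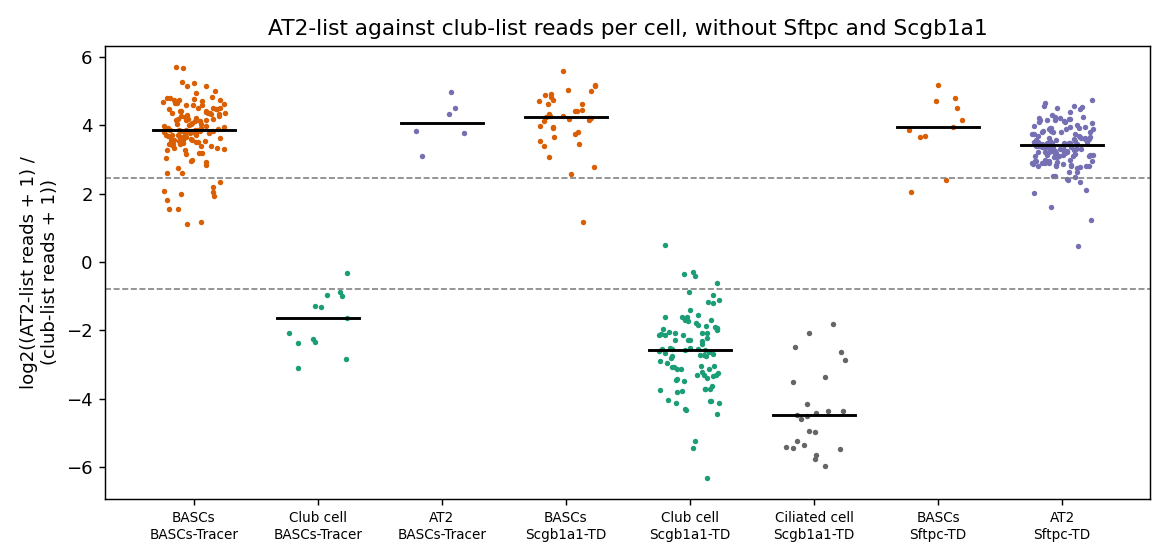
AT2-list reads over club-list reads in each cell (y axis, log2 with 1 read added, Sftpc and Scgb1a1 left out), at 100000 reads per cell, by sub-type and line. Points are cells, black bars medians and dashed lines the 95th percentile of club cells and the 5th percentile of AT2 cells; BASCs of all lines sit with AT2 cells, with medians of 3.87, 4.25 and 3.96.

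Within Scgb1a1-TD, BASCs and club cells shared line and plates. BASCs carried 15 of 16 AT2 markers 2-fold or more higher (median 5.38), with Lyz1 438-fold, Il33 126.6-fold, Fabp5, a fatty acid binding protein gene, 98.05-fold and Sftpc 63.5-fold higher. The club pool of Sftpc was raised by a few cells (219.7 to 165660 CPM over cells). All 7 MHC class II genes (4.90) and 13 of 14 lipid and sterol synthesis genes (2.04) lay higher, among them the desaturase gene Scd1 at 14214 against 611 CPM. Club markers were lower for 19 of 20 (median -4.62). Scgb1a1 was 73.5-fold, Scgb3a2 337-fold, Scgb3a1 587-fold and Aldh1a1 325-fold lower. Xenobiotic metabolism (-3.67, 14 of 15 lower) and airway secretory genes (-4.52, 9 of 12 lower) followed, with the mucin gene Muc5b 296-fold and the ceruloplasmin gene Cp 283-fold lower. The directions of Sftpc and Scgb1a1 held in all 9 plate pairs. The median of all measured genes was -0.12.

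Ciliated cells of the same line were set apart from club cells by the genes of motile cilia. All 18 ciliated markers lay higher, with a median of 6.97, against 0.74 for all measured genes. Foxj1, the regulator of motile cilia (chromosome 11, 116330704 to 116335399), was 349 against 2.35 CPM, the dynein gene Dnah5 542 against 1.52 CPM and Cfap69 362-fold higher. Efcab1, Ccdc78, Vwa3a, Cfap74, Spag17 and Tuba1a were 293-fold to 355-fold higher. Of 20 club markers 15 lay lower (median -2.79), with Scgb1a1 at 19889 CPM, and 13 of 16 AT2 markers lay lower (-2.11). Cyp2a5 and Cyp2b10 went the other way, as did Cyp2s1 of the xenobiotic list at 2809 against 62.4 CPM. Shared surfactant genes (-3.33) and host defence genes (-3.87) lay lower, with Bpifa1 408-fold lower. Notch pathway genes had a median of 1.90, with the ligand genes Jag2 at 76.3 against 0.0720 CPM and Jag1 at 338 against 55.6 CPM. Of 8 progenitor-associated genes 7 lay higher (1.95), including Cd24a at 2441 against 455 CPM and Prom1 at 404 against 17.1 CPM. The pooled Scgb1a1 level of ciliated cells rested on 2 cells of plate 3 with 158993 and 213332 CPM, while all others held 92.9 to 3097 CPM.

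The 11 BASCs of Sftpc-TD were close to the AT2 cells of the line in AT2 markers, of which 15 of 16 lay within 2-fold (median -0.03). Scgb1a1 was 6.58-fold higher at 8464 against 1285 CPM, a pooled level carried by few cells (112.7 to 130015 CPM, median cell 2531 CPM), Cyp2f2 was 231 against 69.3 CPM, and Sftpc was 1.04-fold higher. Of 14 measured club markers 6 lay higher and Aldh1a1 lower (median 0.45), though Cckar and Krt15 among the 6 were lower in all plate pairs, and Scgb3a2 was 10.02 against 9.82 CPM. AT1 markers were lower for 10 of 13 (-1.81), with Pdpn at 0.0796 against 24.6 CPM and Akap5 at 0.477 against 45.3 CPM. These pools rest on few cells: Pdpn had a read in 9.09% of BASCs and 16.1% of AT2 cells, and Akap5 in 27.3% and 37.6%. Lmo7, with a read in 100% and 99.3% of cells, stood at 91.4 against 323 CPM. The sterol genes Sqle (274 against 95.3 CPM), Idi1 and Hmgcs1 were higher, and lipid and sterol synthesis had a median of 0.46. The median of all measured genes was -0.33. All 6 pan-leukocyte genes lay higher (5.58), and alveolar macrophage genes had a median of 3.31. A lone cell of plate 5 held 6680 CPM of these leukocyte markers, and without such cells the log2 ratio of Chil3 went from 8.15 to -0.11 and that of Plek from 4.35 to -1.11. Pold1, Vav3, Clec14a, Pla2g6, Pacs1, Zfp568 and Cpsf2 were also among the 10 highest, and Asph, Nrep, Ldlrad3 and Cipc among the 10 lowest, at 39.3-fold to 52.7-fold.

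BASCs of the different lines shared the AT2 programme, while the pooled level of some club genes differed. Between BASCs of BASCs-Tracer and of Scgb1a1-TD, AT2 markers had a median log2 ratio of 0.01 with 14 of 16 within 2-fold. Scgb1a1 was 3.81-fold higher and Sftpc 1.48-fold lower in BASCs-Tracer. The Scgb1a1 direction held in all 6 plate pairs, with a log2 ratio of 1.45 on plate 2, which held both. On that plate the 5 BASCs of Scgb1a1-TD had 1895 to 7061 CPM of Scgb1a1, inside the range of 590 to 88020 CPM in BASCs of BASCs-Tracer. Club markers were higher for 7 of 16 (median 0.70), against 0.18 for all measured genes. Immediate early genes were higher for 5 of 15 (0.82), including the heat shock gene Hspa1a (20.4-fold), and the chemokine genes Cxcl2 (20.4-fold) and Cxcl1 (12.6-fold) followed. Ccrl2 was 33.5-fold, the thrombin receptor gene F2r 24.3-fold, Pttg1 20.1-fold and Thbs1 7.54-fold higher, and Gpx3, a secreted glutathione peroxidase gene, was 10.01-fold lower. AT1 markers were higher for 5 of 12 (0.91), MHC class II genes had a median of 0.54 and lipid and sterol synthesis genes one of -0.25. Pan-leukocyte genes had a median of 3.27, and endothelial genes one of -1.01 that became 1.47 without plate 3.

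Against the 11 BASCs of Sftpc-TD, BASCs of BASCs-Tracer again had level AT2 markers (median -0.02) and higher club markers for 7 of 17 (0.66, against 0.35 for all genes). Cyp2f2 was 1273 against 231 CPM and Scgb3a2 150.975 against 10.02 CPM, while Scgb1a1 was 1.59-fold higher in the pool but changed sign between plate pairs. Pigr stood at 180 against 0.477 CPM and Cldn4 at 81.3 against 0.0796 CPM. AT1 markers were higher for 6 of 12 (1.24), and pan-leukocyte genes had a median of -2.57 with the leukocyte-marked cell of Sftpc-TD included. BASCs of Scgb1a1-TD and Sftpc-TD had an AT2 median of -0.08 and a club median of 0.38 (0.11 for all genes), which became -0.33 when each cell counted alike. Scgb1a1 was 2.41-fold lower in the pool of Scgb1a1-TD, but median cells were close (2014 against 2531 CPM), and Sftpc was 1.54-fold higher. Gpx3 was 706 against 1.11 CPM and Ly6a 312 against 23.5 CPM. Arntl stood at 77.4 against 0.318 CPM and Tef at 1.21 against 135.1 CPM.

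**Figure D4:**
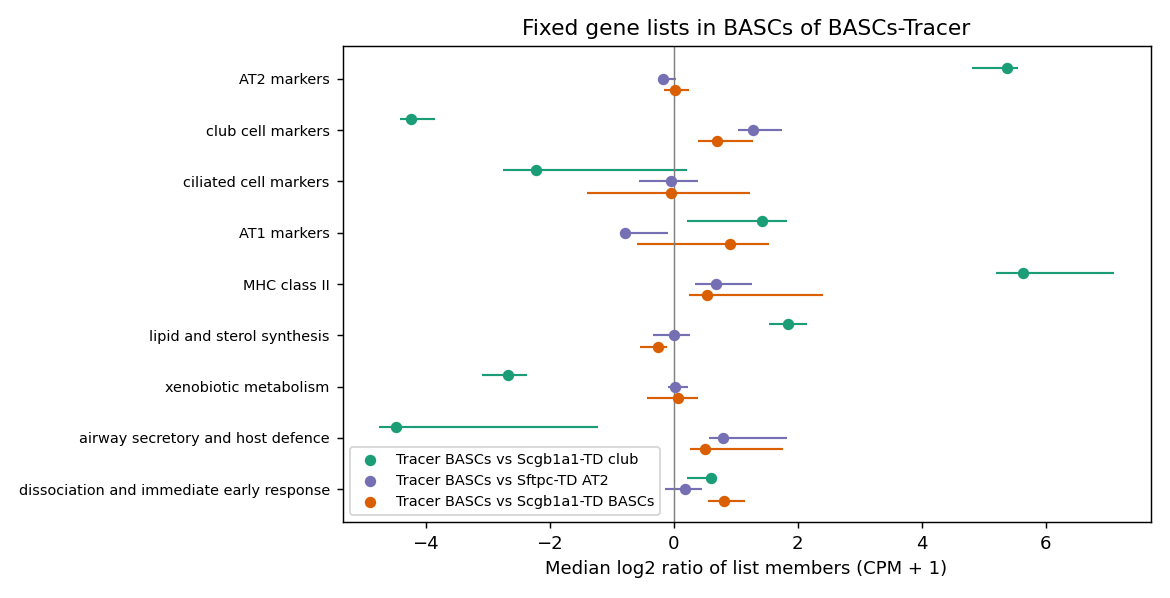
Median log2 ratio (x axis, CPM with 1 added) of 9 fixed gene lists (y axis) in BASCs of BASCs-Tracer against club cells of Scgb1a1-TD, AT2 cells of Sftpc-TD and BASCs of Scgb1a1-TD. Points are pooled values and lines the range over plate pairs; AT2 markers sit at 5.37, -0.17 and 0.01 and club markers at -4.24, 1.27 and 0.70.

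Whole lines, each a mixture of the annotated types, were also set against each other. BASCs-Tracer against Scgb1a1-TD had 12 of 16 AT2 markers higher (median 1.48, or 2.47 on plate 2 alone), 16 of 20 club markers lower (-2.40) and all 18 ciliated markers lower (-4.81). MHC class II genes were higher for 6 of 7 (2.10), xenobiotic metabolism genes lower for 12 of 15 (-1.47) and host defence genes lower for 8 of 12 (-3.94). Scgb1a1 was 5.74-fold lower and Sftpc 2.27-fold higher. Scgb3a1 was 313-fold and Bpifa1 251-fold lower, while Cxcl1 (24.5-fold) and Myc (9.66-fold) lay higher. BASCs-Tracer against Sftpc-TD had all 16 AT2 markers within 2-fold (-0.31) and 13 of 18 club markers higher (2.42). Scgb3a2 was 128.3-fold, Cyp2f2 48.03-fold, Scgb1a1 16.2-fold and Cldn10 15.9-fold higher, xenobiotic metabolism genes were higher for 7 of 15 (0.94), and Sftpc was 1.04-fold lower. The 15 club cells of BASCs-Tracer weighed in these values, with Scgb3a2 at 11009.5 CPM against 150.975 CPM in its BASCs, for which the xenobiotic median was 0.02. With 10 CPM added before the log the club median was 1.19.

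Scgb1a1-TD against Sftpc-TD gave the widest distance, with 18 of 20 club markers higher (median 5.30), all 18 ciliated markers higher (6.20) and 14 of 16 AT2 markers lower (-1.78), against 0.14 for all measured genes. Scgb3a2 was 1275-fold, Scgb3a1 741-fold and Scgb1a1 92.9-fold higher, and Sftpc stood at 68099 against 161053 CPM. Host defence genes were higher for 10 of 12 (5.56) and xenobiotic metabolism genes for 12 of 15 (2.48), while 6 of 7 MHC class II genes were lower (-2.04). On plate 4, which held both lines, the log2 ratio of Scgb1a1 was 6.91 and that of Sftpc -0.98. Sex-linked transcripts also parted the lines: Xist stood at 6.59, 4.05 and 211 CPM in BASCs-Tracer, Scgb1a1-TD and Sftpc-TD, and Y-linked Ddx3y at 77.4, 65.1 and 0.0391 CPM.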

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

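All values in this part come from recomputing the results under other choices, and the settings on club or AT2 cells of the same line, leukocyte reads and 1000 reads were chosen after the results were seen. Of 345 values for 43 main results 311 stayed within the limit set for their kind and 34 moved. Named genes gave 2360 values for 240 results, with 12 reversed and 551 moved, and the other lists gave 2156 values for 200 results, with 15 reversed and 278 moved. AT2 markers between BASCs of BASCs-Tracer and AT2 cells ranged from -0.24 to 0.02 and club markers from 0.89 to 1.78. Unless a cause is given, the cause was not tested. No paired analysis was possible because replicate numbers only follow accession order and the results come from no test; groups that shared a plate were compared within it only as ratios.

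Shares that rest on 1 cell became 0% without its plate: ciliated cells of BASCs-Tracer without plate 2 and AT2 cells of Scgb1a1-TD without plate 4. With sub-types set by the fixed lists, which hold no class of BASCs, BASCs-Tracer had 96.9% AT2, 3.13% club and 0% ciliated cells, Scgb1a1-TD had 27.5% AT2 and Sftpc-TD 100% AT2. Cells with both Scgb1a1 and Sftpc fell, by construction, to 86.3% at 100 reads and 27.5% at 1000 reads in BASCs-Tracer, and to 46.8% and 5.77% in Scgb1a1-TD. Sftpc-TD had 93.7% at 1 read, 27.04% at 100 and 2.52% at 1000, with 64.2% without plate 4 and 93.75% without plate 5. Median genes in BASCs-Tracer were 2853.5 when 5 or more reads were needed. With Sftpc and Scgb1a1 counted, 21.1% of BASCs lay between club and AT2 cells.

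Between lines, the AT2 median of BASCs-Tracer against Scgb1a1-TD was 2.47 on plate 2 only. The club median of BASCs-Tracer against Sftpc-TD was 1.19 with 10 CPM added, which shrinks ratios of low genes, and 1.24 with no filter on low genes. For Scgb1a1-TD against Sftpc-TD the club median was 3.66 with 10 CPM added. Alveolar macrophage markers there reversed from -1.71 to 0.25 without plate 5, 0.57 on plate 4 only and 0.16 without leukocyte reads.

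For BASCs of BASCs-Tracer against club cells, 10 CPM added gave an AT2 median of 4.57 and a club median of -3.50. Without plate 3 the club median was -3.63 and the ciliated median 1.04. Against club cells of the same line the medians were 3.14 for AT2, -2.68 for club, -0.024 for AT1, -0.18 for alveolar macrophage and 3.09 for proliferation genes (0.17 over the 12 members measured against Scgb1a1-TD), and Scgb3a1, Bpifa1 and Ltf were at 0.042, 1.41 and 0.25. Against AT2 cells of the same line, of which there were 6, Ly6a was at -0.70, Xist 1.47, BC018473 4.02, Dbp 3.86, Bmi1 3.27 and Cipc 3.42, all reversed.

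Within Scgb1a1-TD, BASCs against club cells had an AT2 median of 4.75 and a club median of -3.56 with 10 CPM added, and without plate 3 a club median of -3.73 and a ciliated median of 0.51. Ciliated against club cells had an AT2 median of -2.72 with median-of-ratios scaling and -2.72 without mitochondrial and the most abundant genes, and a club median of -2.16 with 10 CPM added. Without leukocyte reads, BASCs of Sftpc-TD against AT2 cells had endothelial markers at -0.19, Chil3 at -0.11 and Plek at -1.11, because 1 cell with leukocyte reads had carried them. Between BASCs of Scgb1a1-TD and Sftpc-TD, Chil3 was then at 1.81, and the club median was -0.33 with the mean over cells. Endothelial markers between BASCs of BASCs-Tracer and Scgb1a1-TD were at 1.47 without plate 3. Club cells of BASCs-Tracer against those of Scgb1a1-TD had endothelial markers at 0.66 with the mean over cells, 0.39 without plate 2 and 2.54 without plate 3, against -1.39. With no filter on low genes MHC class II was at -0.11 and the Wnt pathway at -0.37.

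Some settings were not run because a side held fewer than 5 cells: BASCs-Tracer and Sftpc-TD shared no plate, and BASCs of Sftpc-TD without plate 5 were 4 cells. Depth limited presence calls to the 468 cells with enough reads.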

Other observations

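The tests and added pairs in this part were chosen after the results were seen. Club cells of BASCs-Tracer (15 cells) differed from club cells of Scgb1a1-TD (97 cells) despite the shared annotation. They had less of the host defence programme, with 8 of 12 genes 2-fold or more lower (median -3.56): Bpifb1 stood at 0.690 against 1943 CPM, Reg3g at 1.93 against 2201 CPM and Scgb3a1 at 5.11 against 3362 CPM. Club markers were lower for 9 of 21 (median -0.71), with Scgb1a1 at 139724 against 258576 CPM. AT2 markers were higher for 10 of 16 (1.41), with Sftpc at 14297 against 4062 CPM. Both Sftpc pools came from uneven cells, at 459.5 to 85855 CPM in BASCs-Tracer and 219.7 to 165660 CPM in Scgb1a1-TD. Chia1, an acidic chitinase gene, was 14048 against 294 CPM, and Myc 712 against 17.4 CPM. Areg, which encodes an epidermal growth factor receptor ligand, was 232 against 2.71 CPM, Cxcl1 276 against 5.07 CPM and Plaur 477 against 23.5 CPM. Immediate early genes were higher for 6 of 16 (0.87) and proliferation genes lower for 10 of 11 (-2.60).

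Club genes in BASCs of BASCs-Tracer could come from RNA of club cells outside the cell, which would add all club genes in the same proportion. After the level in AT2 cells of plate 5 was subtracted from that in BASCs, Scgb1a1 stood at 8.54% of the level in club cells of the same line, Hp at 8.02%, Cyp2f2 at 5.08%, Aldh1a1 at 1.38% and Scgb3a2 at 1.33%. With club cells of the same line, the ratio between highest and lowest share was 10.4 on plate 1 and 3.34 on plate 2. With club cells of Scgb1a1-TD it lay far over the limit of 4 (Hp 7.92%, Scgb3a1 0.137%). Gsta3 stood there at a set floor of 0.00131%, since those AT2 cells held 72.9 CPM and BASCs 59.1 CPM. The AT2 baseline came from another line and plate, so unequal shares can also come from line differences. They cannot count against RNA from outside added to a cell's own, so this explanation stays open. BASCs had 0.833 of the genes per cell of the richer of club and AT2 cells, but a well with AT2 RNA and a small club share would not exceed that number either, so 2 cells in a well also stays open. In AT2 cells of Sftpc-TD, 95% of those on plate 4 had a Scgb3a2 read, against 30.3% on plate 5, which is consistent with carry-over from the Scgb1a1-TD wells of plate 4.

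Genes apart between BASCs of BASCs-Tracer and AT2 cells of Sftpc-TD may reflect line, sex or handling instead of cell type. Within BASCs-Tracer, against its 6 AT2 cells, 6 of the 10 higher genes and 3 of the 10 lower genes stayed 2-fold or more apart, and 8 had been needed to set the explanation aside, so it stays open. Esr1 (96.9 against 2.20 CPM), Pigr (180 against 4.81 CPM) and Cldn4 (81.3 against 1.201 CPM) were among those kept, as was Y-linked Eif2s3y (2.06-fold), which argues nothing against a difference in sex. The higher genes not kept were Cd24a (1.99-fold higher), Scgb3a2 (1.70-fold), Ddx3y (1.25-fold) and Ly6a, which lay lower. Of the lower genes not kept, Dbp, Bmi1, BC018473 and Cipc stood at 0.200 to 0.601 CPM in those 6 cells, which is few reads.

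Genes higher in BASCs of BASCs-Tracer than in both other types may show a line-wide difference rather than one of the BASCs annotation. Within Scgb1a1-TD, 5 of the 10 genes were 2-fold or more higher in BASCs than in club cells, which leaves this open. BASCs there carried the AT2 programme, so a gene higher in AT2 than in club cells would pass as well. Of the 5, Rerg was at 19.6 CPM in AT2 cells of Sftpc-TD against 0.216 CPM in the club cells. Hdc was at 175 against 8.57 CPM. Hdc, Rerg and Heatr1 stood at 474, 67.1 and 79.1 CPM in BASCs of Scgb1a1-TD and at 368, 91.4 and 84.97 CPM in BASCs of Sftpc-TD, but AT2 cells of BASCs-Tracer also held Hdc at 367 CPM and Rerg at 51.7 CPM. Myc, Thbs1 and Ier5 were also 2-fold or more higher in club cells of BASCs-Tracer than in those of Scgb1a1-TD.

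Xist reached 10 CPM in 49 of 64 and 78 of 96 Sftpc-TD cells on plates 4 and 5, where 0 cells reached 10 CPM of Y-linked genes. Y-linked genes reached it in 80 of 96 and 41 of 64 BASCs-Tracer cells on plates 1 and 2, and in 29 of 32, 76 of 96 and 23 of 32 Scgb1a1-TD cells on plates 2, 3 and 4. Esr1 was 130.5 CPM in BASCs-Tracer, 162 CPM in Scgb1a1-TD and 0.0147 CPM in Sftpc-TD, so it was higher in both lines that need the Cre than in the line with the Dre alone. Within BASCs-Tracer, BASCs held 96.9 CPM and AT2 cells 2.20 CPM. Reads of a recombinase transgene with an oestrogen receptor sequence were not told apart from Esr1. Dbp and Arntl, picked after the data were seen, also differed by line, with Dbp at 17.6, 3.48 and 80.1 CPM and Arntl at 28.7, 43.7 and 0.259 CPM in the same order. The cell of BASCs-Tracer annotated as ciliated held 72979 CPM of Scgb1a1 and 95578 CPM of Sftpc. The BASC of Sftpc-TD with leukocyte reads held Ptprc at 1928 CPM, Chil3 at 8053 CPM, Cd209a at 1712 CPM and Sftpc at 64714.5 CPM, over 7262 genes.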
